A study of Nilaparvata lugens with 6 samples.

How the data were processed

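RNA of fed and starved Nilaparvata lugens females was extracted with a column kit and amplified and labelled as Cy3 or Cy5 cRNA, per the labels' protocols. It was hybridised to 6 Agilent arrays of 45220 spots, 1417 of them control spots. On 3 arrays feeding RNA carried Cy5 and on 3 it carried Cy3, per the labels. The deposited scanner files hold mean spot intensity and median local background intensity per channel, made with Agilent Feature Extraction 9.5 per the submitters' processing notes and the file headers. Per the file headers, the same files hold processed intensity values, background-subtracted and dye-normalised by that program, and the log10 ratio of Cy5 over Cy3. The authors' deposited value table holds log10 ratios of 35167 probes, all with names that begin with Ta. They differed from the scanner files' log10 ratios by at most 0.00499, as rounding would give, so its scale and direction (Cy5 over Cy3) are known. Its median was 0 in each of the 6 columns; beyond the program's dye normalisation, no centring was found. All of its columns were used.

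Scanner files were read in R 4.3.3 with limma 3.58.1. Spots that the scanner software flagged as feature outliers or as having a non-uniform background in either channel were left out before background correction (997 probe spots over the 6 arrays, between 97 and 213 per array). Background was corrected with normexp and an offset of 50, and each array was normalised by loess with control spots at weight 0. The design fixed before the data were examined leaves out outlier flags without naming them. The ratios were first computed with the spots of non-uniform background still in the normexp model, and these spots were taken out after the counts of that version had been seen. The reason was 1 array of replicate 2, with feeding RNA in Cy3, on which 7 flagged spots lay over 1000 intensity units below their local background. With all flagged spots left in the model, the modelled Cy5 background mean was -444, against -15.6 without them. The array's median log2 intensity was 9.28, against 8.26. Leaving out the 7 spots alone was not tried. The counts of both versions are given with the alternatives.

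Probes were kept where feeding or starvation RNA was well above background in at least 3 of its 6 channels, and 83 such probes with no usable spot in 1 replicate were left out. Array ratios were turned to feeding over starvation, and the 2 arrays of a dye swap were averaged and counted as 1 replicate, so that a dye effect cancels. The 3 replicate log2 ratios were tested against 0 with lmFit and eBayes in limma, with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 1.86. For counts per target, which stand in for genes, the brighter of the probes of a target was used. Feeding and starvation RNA of 1 number share both arrays, which is where the pairing comes from. Single-channel deviations from the group means correlated at 0.51, 0.68 and 0.11 for replicates 1, 2 and 3 across probes. Levels of single RNA samples came from both channels after loess and Aquantile scaling. The spike-in controls had a slope of observed on expected log ratio between 0.952 and 0.962, as the file headers give it.

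The rule for probes named in the text took the 2 largest ratios in each direction with the same sign on all 6 arrays, among the brightest probes of each target and those past the threshold. Since none passed, it was applied without the threshold. Gene names were not given: the probe descriptions hold none, and the reference table used here shares no identifier with the clone names. The planned tests of gene lists and cell type marker lists were therefore not run. Instead, the first 4 letters of the clone names were used as groups, a choice made after the data had been seen. Over-representation was tested with Fisher's exact test over targets, again over groups of similar sequence, and with an exact Mantel-Haenszel test within 5 classes of intensity. Groups joined probes of 1 target or with at least 90% identity over at least 45 bases in BLAST+ 2.17.0, linked with igraph 2.1.4. P-values were adjusted over the 105 tests of each kind. Shifts of whole codes were tested with camera and fry in limma. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

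The test was tried on simulated data with 24192 probes, of which 50 were changed at each of 4 sizes. For feeding against starvation it found 62% of the probes changed by 1 on the log2 scale, 84% of those changed by 2, 96% of those changed by 3 and 100% of those changed by 4, at an adjusted p of 0.05, with 6 false calls. The simulation drew the spread of a probe independently of its change. In the data, the probe Ta05344_792 had an SD between replicates of 1.50, against a median of 0.126 over the probes kept. It did not pass at a log2 ratio of 4.03, so these shares may overstate what the test finds in the data. The simulation also changed few probes, whereas 16.4% of the probes kept had an unadjusted limma p under 0.05. That difference could move the shares the other way. Alternatives covered the background correction, normalisation within and between arrays, filters on dim probes, the authors' value table, the treatment of dye swaps, pairing, slide, each replicate left out, the variance prior, the probe of a target and the threshold. Added after the data had been seen were an adjusted p under 0.10, only the probes of the value table, scale normalisation between arrays and normexp on all spots.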

Results

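Young females of the brown planthopper Nilaparvata lugens, a sap-sucking pest of rice, were either left to feed on rice seedlings or given only water for 24 h, and RNA of both groups was compared on 2-colour oligonucleotide arrays. The strain was Izumo, and each group had 3 RNA samples. Feeding and starvation RNA with the same replicate number were hybridised together on 2 arrays with the dyes exchanged, which gave 6 arrays and 3 replicate log2 ratios of feeding over starvation. A positive log2 ratio means a higher signal in fed females. The labels do not say how many insects went into an RNA sample or whether the 3 pairs came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The array held 43803 probes of 60 bases for 21902 targets, and 24192 probes of 13641 targets were bright enough to be compared. Of the probes whose names begin with Ta, 67.5% were kept, against 5.4% of those that begin with Ha. The share of probes well above background ranged from 51.9% to 56.6% for feeding RNA and from 51.2% to 54.7% for starvation RNA. The number of RNA samples, 3 per group, limits the precision of every value given here.

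The first question was which transcripts differed between fed and starved females. A set of 88 probes for 54 targets was at least 2-fold higher in feeding in all 3 replicates, and 25 probes for 17 targets were at least 2-fold lower in all 3. The median log2 ratio of the higher set was 1.32 in replicate 1, 1.52 in replicate 2 and 1.28 in replicate 3. The median of the lower set was -1.19, -1.54 and -1.63 in the same replicates. Both probes of the target were in the set for 34 targets of the higher set and 8 targets of the lower set. These counts were 128 higher and 300 lower without replicate 1, 144 and 52 without replicate 3, and 173 and 67 with the scanner software's processed signals, so the balance of directions rested on replicate 1. No probe passed an adjusted p of 0.05 in the limma test of the 3 replicate ratios, and the lowest adjusted p, shared by 66 probes, was 0.0587. At an unadjusted p under 0.05 the same limma test gave 3961 probes, 2256 higher and 1705 lower in feeding, against 1210 expected by chance. That count was 2125 without replicate 2, and 3807 and 3752 without replicates 1 and 3. At an adjusted p under 0.10, a threshold chosen after the first was seen to give none, there were 845 probes, of which 547 were higher and 298 lower. With 1 replicate left out no probe reached 0.10. The lowest limma adjusted p was then 0.104, 0.373 and 0.172 without replicates 1, 2 and 3. Of these 845 probes, 844 had the same sign on every array measured, which their choice by a low p largely fixes. Their median absolute log2 ratio was 0.68. The count of 0 depended on the setting, since 83 probes passed 0.05 when only probes well above background in both channels of all 6 arrays were tested, 138 passed with a trended and robust variance prior, and 22 passed without the pairing. The lowest limma adjusted p in these settings was 0.0487, 0.0469 and 0.0434, so all of these probes lay just under the threshold. A fit of all 6 arrays with a random replicate block gave 1770, treating the dye-swapped arrays as separate observations.

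The files pair probes with cDNA clone names and with no gene name or description, so the gene lists fixed beforehand (digestion, metabolism, reproduction, cell type markers and others) could not be tested. By the rule fixed for probes without gene names, applied without its p threshold because none passed, 2 probes higher and 2 lower in feeding are given by name. The probe Ta05344_792 (clone NLMB0463, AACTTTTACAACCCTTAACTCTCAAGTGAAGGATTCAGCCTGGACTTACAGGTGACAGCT) was higher in feeding by a log2 ratio of 4.03 ± 0.62 (SE, n = 3; limma adjusted p = 0.0988), a 16.4-fold difference. Its log2 ratios in replicates 1, 2 and 3 were 2.77, 3.64 and 5.69, and the other probe of its target gave a mean of 3.94. The probe Ta01420_944 (clone NLEA1403, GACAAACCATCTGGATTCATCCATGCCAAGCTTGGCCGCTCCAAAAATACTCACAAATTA) was higher by a log2 ratio of 3.17 ± 0.49 (SE, n = 3; limma adjusted p = 0.0982), with replicate values of 2.02, 4.35 and 3.13. The other probe of that target gave 2.65. The probe Ta04859_209 (clone NLMA2379, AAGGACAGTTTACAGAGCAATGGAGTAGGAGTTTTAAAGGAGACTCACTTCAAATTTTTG) was lower in feeding, at a log2 ratio of -2.31 ± 0.53 (SE, n = 3; limma adjusted p = 0.167). Its replicate values were -0.96, -2.52 and -3.46, and the other probe of the target gave -2.67. The probe Ta05520_235 (clone NLMB1669, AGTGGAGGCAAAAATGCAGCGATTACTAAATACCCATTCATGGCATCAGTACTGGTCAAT) had a log2 ratio of -2.00 ± 0.48 (SE, n = 3; limma adjusted p = 0.182). Its replicate values were -0.79, -2.13 and -3.09. Feeding RNA was well above background in 4 of 6 channels for this probe and in 2 of 6 for the other probe of the target, which gave -1.91. The size of both ratios is therefore uncertain. The log2 ratio of Ta05520_235 was -2.15 with no background correction, -1.76 with normexp on all spots and -3.60 with the scanner software's processed signals. The rule required these 4 probes to have the same sign on all 6 arrays, and none passed the adjusted p of 0.05. Neither of the lower probes was 2-fold lower in replicate 1, so neither belongs to the set at least 2-fold lower in all 3 replicates. The clones of 3 of them carry the codes NLMA or NLMB, which were over-represented among probes whose direction differed between replicates. Over the 10551 targets with both probes kept, the log2 ratios of the 2 probes correlated at r = 0.89 across targets, which are not independent replicates. Of 155 targets with both probes at least 2-fold apart on average, 154 had both in the same direction. If the number in a probe's name is its position in the target, some pairs of probes overlap. Overlapping probes would agree in part by construction, and how many pairs overlap was not counted.

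The clone names begin with 1 of 21 4-letter codes, whose meaning the files do not give, and these codes were used as groups after the data had been seen. Among the 211 targets with any probe lower in feeding at an adjusted p under 0.10, clones coded NLTH made up 59 (28.0%), against 9.3% of all targets compared. By the brighter probe of each target alone, at the same adjusted p, 44 NLTH targets were lower and 40 were higher, so its members went both ways. For the 59 of 211 targets the odds ratio was 3.92 (Fisher's exact test, two-sided, adjusted p = 1.43e-13 over 105 tests of 5 sets and 21 codes). It was 4.05 (adjusted p = 6.77e-12) when targets of similar sequence were counted once, and 3.03 (adjusted p = 4.9e-09) within 5 classes of signal intensity. Clones coded NLEA made up 6 of those 211 targets (2.8%), against 11.9% of all targets, at an odds ratio of 0.214 (adjusted p = 7.82e-05) and 0.247 (adjusted p = 0.00122) within the 5 classes of intensity. Clones coded NLHT made up 27 of the 211 (12.8%), against 5.7%, with an odds ratio of 2.5 (adjusted p = 0.0011) that did not pass within the 5 classes of intensity (adjusted p = 0.0549). In the smaller set of 17 targets at least 2-fold lower in every replicate, 6 were NLNB clones (35.3%, against 8.2%; Fisher's exact adjusted p = 0.0176), but counting similar sequences once gave 4 of 15 (adjusted p = 0.21). No code shifted as a whole in the mean ratio, the lowest camera adjusted p over the 21 codes being 0.243, with 0.834 under an estimated correlation and 0.369 for fry. For NLTH the adjusted p was 0.534 by camera and 0.501 by fry. Fisher's exact and Mantel-Haenszel tests count targets as independent, although all were called from the same 3 replicate ratios. Their p-values therefore do not measure the spread between RNA samples.

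**Figure D1:**
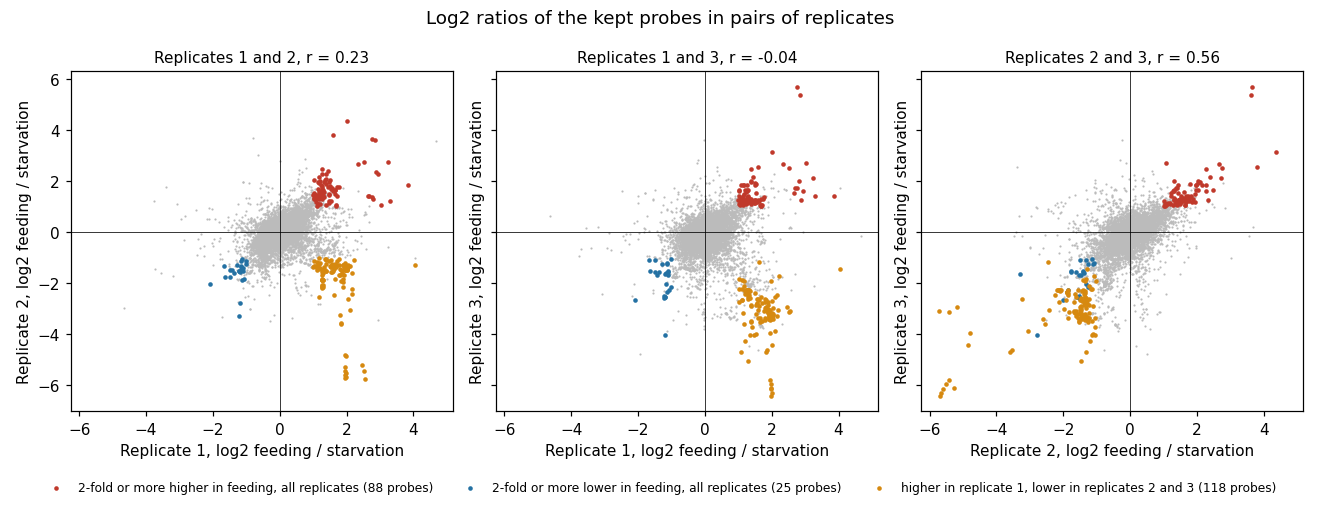
Log2 ratio of feeding over starvation of each of the 24192 probes kept, in each pair of replicates (log2 units on both axes); coloured points are the 88 probes at least 2-fold higher, the 25 at least 2-fold lower in all 3 replicates, and the 118 higher in replicate 1 but lower in replicates 2 and 3. The correlation across probes was 0.23 for replicates 1 and 2, -0.04 for replicates 1 and 3 and 0.56 for replicates 2 and 3.

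Another set of probes differed between fed and starved females in opposite directions among the replicates. These 118 probes for 79 targets were at least 2-fold higher in feeding in replicate 1 and at least 2-fold lower in replicates 2 and 3, with median log2 ratios of 1.72, -1.46 and -3.02. The opposite pattern, lower in replicate 1 and higher in replicates 2 and 3, was seen in 0 probes, and the other 4 patterns with mixed signs in 1 to 3 probes each. All 118 probes kept the same signs on every array measured, and none had an unadjusted limma p under 0.05 in the test of the mean. Both follow largely from the choice of these probes by their replicate ratios. Clones coded NLMA made up 33 of the 79 targets (41.8%), against 5.2% of all targets, at an odds ratio of 13.5 (Fisher's exact adjusted p = 5.61e-20). Clones coded NLMB made up 23 of the 79 (29.1%), against 3.2%, at an odds ratio of 13.2 (Fisher's exact adjusted p = 9.14e-15). With similar sequences counted once, the 79 targets formed 34 groups, of which 16 were NLMA (adjusted p = 1.59e-10) and 6 were NLMB (adjusted p = 0.0141). Within the 5 classes of intensity the adjusted p was 9.8e-19 for NLMA and 1.06e-13 for NLMB. No NLEA clone was among the 79 targets, against 11.9% of all targets, though this did not pass with similar sequences counted once (adjusted p = 0.209). The set was chosen after the replicate ratios had been seen. These tests of codes also count targets as independent, so their p-values do not measure the spread between RNA samples.

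**Figure D2:**
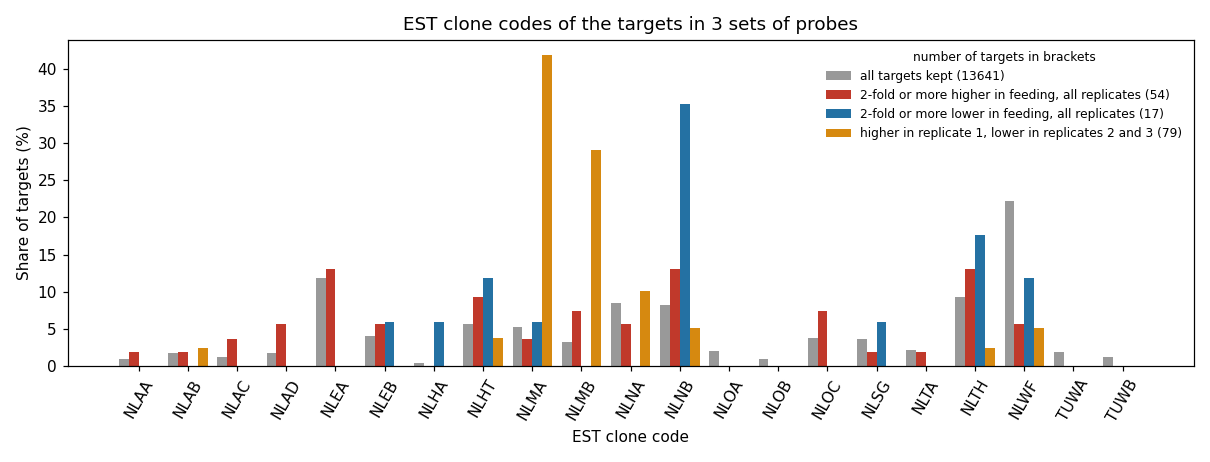
Share of targets (%, bars from 0) with each of the 21 clone codes among all 13641 targets compared and in the sets of 54, 17 and 79 targets. NLMA (41.8%) and NLMB (29.1%) stand out in the set that was higher in replicate 1 and lower in replicates 2 and 3.

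The levels of the 6 RNA samples show which RNAs differed over these 118 probes, whose choice by their ratios largely fixes the direction of these differences. Feeding RNA of replicate 1 was higher than that of replicate 2 in 118 of 118 probes, by a median of 1.82 on the log2 scale, and higher than that of replicate 3 in 118 of 118, by 2.58. Starvation RNA of replicate 1 was higher than that of replicate 2 in 0 of 118 probes, with a median difference of -1.35, and the difference from replicate 3 was -1.97. Replicates 2 and 3 differed as well, feeding RNA of replicate 2 being higher in 107 of 118 probes (median difference 0.70) and starvation RNA in 12 of 118 (-0.56). The median log2 intensity of feeding RNA was 11.85, 9.75 and 9.10 in replicates 1, 2 and 3, and that of starvation RNA 10.14, 11.64 and 12.08. Between replicates of the same RNA, the median differences over the 88 probes of the higher set, chosen for like ratios in all replicates, ranged from -0.26 to 0.20, and those over the 25 probes of the lower set from -0.47 to 0.21. The medians of the lower set itself were more spread, with starvation RNA at 12.09, 13.22 and 11.91 in replicates 1, 2 and 3.

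**Figure D3:**
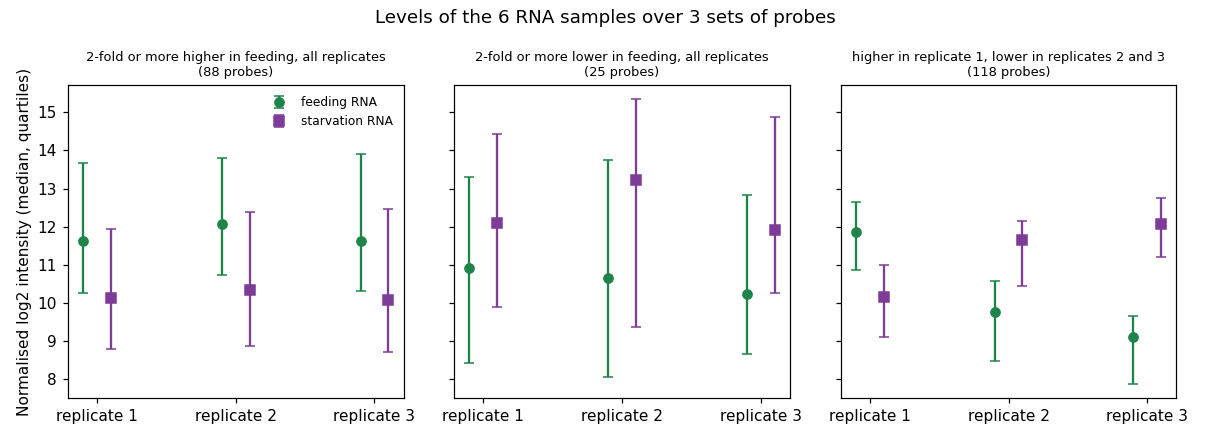
Normalised log2 intensity of feeding (circles) and starvation (squares) RNA in each replicate over 3 sets of probes, where points are medians and bars span the quartiles over probes. In the right panel, feeding RNA lies above starvation RNA in replicate 1 (11.85 against 10.14) and below it in replicates 2 (9.75 against 11.64) and 3 (9.10 against 12.08).

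The last comparison asked how well the arrays and replicates went together. The dye-swapped arrays of one replicate correlated at r = 0.82, 0.88 and 0.92 across probes for replicates 1, 2 and 3. Replicates 1 and 2 correlated at r = 0.23 (Spearman's rho 0.39), replicates 1 and 3 at r = -0.04 (rho 0.15) and replicates 2 and 3 at r = 0.56 (rho 0.40); these are correlations across probes, which are not independent replicates. The sign of the ratio was the same in all 3 replicates for 39.8% of the probes, against 25% by chance. Single replicates had 561 probes at least 2-fold higher and 146 lower (replicate 1), 330 and 489 (replicate 2), and 268 and 793 (replicate 3). Replicates 1 and 2 shared slide 1 and replicate 3 was on slide 2. With slide as a block 0 probes passed an adjusted p of 0.05 in limma (3930 at an unadjusted p under 0.05), and within slide 1 alone the count was also 0 (3752 at an unadjusted p under 0.05), while slide 2 held 1 replicate and allowed no test. Both fits leave fewer residual degrees of freedom than the main fit, which also gave 0. These counts therefore cannot tell whether the slide mattered.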

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

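The thresholds of 0.10, the value-table probes, scale normalisation, normexp on all spots, and all settings of the sets defined by 2-fold differences in every replicate were chosen after the results had been seen. The main limma counts were 0 probes, 0 probes at least 2-fold apart and 0 targets at an adjusted p of 0.05. At an unadjusted p under 0.05 the limma test gave 3961 probes and 2253 targets. The counts at the adjusted p were also 0 with no background correction, processed signals, median centring and scale normalisation. They were 0 as well with normexp on all spots (3941 probes at an unadjusted p under 0.05), the authors' table and the value-table probes. Slide as a block and leaving out each replicate gave 0 too, but leave fewer residual degrees of freedom than the 2 of the main fit. Without 1 replicate the lowest limma adjusted p was between 0.104 and 0.373. A threshold of 0.01 could only give 0 again, and Aquantile leaves ratios unchanged by construction. Counts of probes, probes at least 2-fold apart and targets were 83, 67 and 72 with only probes well above background in both channels of all arrays, 138, 95 and 136 with the trended and robust prior, 84, 70 and 80 on the arrays with feeding RNA in Cy5, 121, 86 and 96 on those with feeding RNA in Cy3, and 845, 210 and 511 at an adjusted p under 0.10. With no filter 27 targets passed and 0 probes (5224 at an unadjusted p under 0.05). Without the pairing (no replicate block) the counts were 22, 18 and 29, and with all 6 arrays, a dye term and a random replicate block they were 1770, 325 and 1013; that last fit sets 1 correlation (0.82) for all probes and counts both arrays of a swap, which adds degrees of freedom without adding RNA samples. Apart from these properties of construction, the cause was not tested. The lowest limma adjusted p of a probe lay just above 0.05 (0.0587). It stayed above 0.05 with scale normalisation (0.0568), normexp on all spots (0.0527) and no filter (0.0507). The 113 probes at least 2-fold apart in every replicate became 240 with processed signals and 243 in the authors' table, whose signals carry no offset, and 165 to 428 without 1 replicate. The 428 came without replicate 1 (128 higher and 300 lower), and 196 came without replicate 3. The 118 probes reversed in replicate 1 ranged from 106 to 171 over 12 alternatives, with NLMA and NLMB clones at 69.0% to 73.7%. The lowest dye-swap correlation, 0.82, was 0.56 with median centring, 0.70 with processed signals and 0.74 in the authors' table; the cause was not tested. The 4 named probes kept their direction in every alternative that tested them and passed 0.05 only in the 6-array fit; Ta05520_235, whose feeding signal was near background, moved from -2.00 to -3.60 with processed signals and in the authors' table. Signal over background limits the comparison to the 24192 probes kept. Tests of gene lists were not run, as no gene names were at hand.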

Other observations

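Both tests of other arrangements of the samples have too few arrangements for a share under 0.05. The test by sign was chosen after its result had been seen, as were the tests of an exchange, of the slide and of the arrays of replicate 1, the count of unmatched Ha probes, and the comparison of gaps between codes. At an unadjusted limma p under 0.05 the real signs of the 3 replicate ratios gave 3961 probes, and the highest of the other 3 of 4 sign patterns gave 1055, which turned replicate 1; 1 of 4 patterns, the real one itself, gave as many. In the unpaired fit, 3 of the 10 splits of the 6 RNA samples, the real one included, gave at least the 1818 probes of the real split. The highest other split gave 4026 and put both RNAs of replicate 1 with feeding RNA of replicate 3. Of the splits that part all 3 pairs, as the real one does, the other 3 gave 179, 147 and 656.

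By Pearson's r the log2 ratios of replicate 1 correlated weakly with those of replicates 2 (0.23) and 3 (-0.04), against 0.56 for replicates 2 and 3; by rank the values were 0.39, 0.15 and 0.40, so replicate 1 was apart from replicate 2 only in r, which large ratios weigh on most. An exchange of its feeding and starvation RNA would turn all differences, which is argued against, since 96.1% of the 128 probes at least 2-fold higher in both other replicates also lay above 0 in replicate 1; of the 300 at least 2-fold lower in both, 53.3% lay above 0 there, 118 of them at least 2-fold higher and 25 at least 2-fold lower. The slide cannot be told apart, since the correlation of replicates 1 and 2, on 1 slide, minus that of replicates 2 and 3, on different slides, was -0.32 by r, which goes against it, but -0.01 by rank. Noisy arrays are argued against by the correlation of 0.82 between the dye-swapped arrays of replicate 1. The lowest dye-swap correlation of any replicate was 0.56 with median centring and 0.70 with processed signals, so this argument may be weaker under those settings. The labels name nothing that differs between the replicates, so no biological explanation was tested, and a difference between the insects or RNA samples of replicate 1 and the others stays open.

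The 118 probes higher in replicate 1 and lower in replicates 2 and 3 were mostly NLMA or NLMB clones (72.0%). An artefact of single arrays is argued against by 120 probes picked for the pattern on the arrays with feeding RNA in Cy5. Of these, 100% had the same 3 signs on the other 3 arrays. Repeats of similar sequence enlarge the set, as its 79 targets formed 34 groups, while the 54 targets of the higher set formed 49. They do not make up all of the set, since 34 groups remained. Over the groups the odds ratio was 16.2 for NLMA and 6.82 for NLMB, against 13.5 and 13.2 over targets. Both codes thus stayed over-represented, NLMB less so. A hypothesis is that the RNA samples may hold different amounts of transcripts that clones of these codes have in common: the 1068 other NLMA and NLMB targets, with no probe of similar sequence in the set, shifted the same way in each replicate, the smallest gap to other targets being 0.037 on the log2 scale (95% bootstrap interval 0.020 to 0.046, over targets and not over RNA samples). Gaps of that size in 1 replicate also occurred for other codes (0.086 for NLNB in replicate 2), but the smallest of the 3 gaps was 0.024 for NLMA alone and 0.034 for NLMB alone, against at most -0.005 for the other 19 codes and 0.002 for 171 pairs of them. That gap is far below the ratios of the set itself (medians of 1.72, -1.46 and -3.02), so it does not account for their size. Its origin stays open, as the labels name nothing that differs between the replicates. Both codes had been picked for their share of this set, and targets just short of its 2-fold limits were kept in this comparison. The gap and its rank among the codes may follow in part from that choice, so they are no independent support for the hypothesis.

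Of the probes whose names begin with Ha, which the authors' value table does not list, 463 of 8636 were bright enough to be compared. Their median log2 ratio was -0.03, and 30 of them (6.5%) had an unadjusted limma p under 0.05. A candidate explanation for some of this signal is hybridisation of transcripts that the Ta probes target: 16 of the 463 (3.5%) matched a Ta probe with at least 80% identity over at least 40 bases, against 0.3% of the 8173 others (one-sided Fisher's exact p = 1.64e-11). For the other 447 it cannot be told apart from signal of their own targets, since a Ta probe covers only 60 bases of its transcript.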
